A study of Homo sapiens with 12 samples.

How the data were processed

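Total RNA from 12 samples of 2 Ewing sarcoma cell lines was measured on Illumina BeadChips. Each line had 3 arrays of cells given 0.1% (v/v) DMSO vehicle and 3 arrays of cells given 40 µM NU7441, all taken at 48 h. Per the labels' protocols, cells were grown in RPMI-1640 with fetal bovine serum, RNA was extracted with a Maxwell kit and biotin-labelled cRNA was made with an Illumina TotalPrep kit. The groups and replicate numbers were taken from the sample titles, and each column of the tables was assigned to a sample by its name. In the intensity table the line, a V or T and a number were read as vehicle or treated and the replicate. No label says that the replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. All 6 vehicle titles and no NU7441 title carry a mark (2) whose meaning the labels do not give, so a separate run of the vehicle samples, if it denotes one, cannot be told apart from the treatment.

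Per the file headers, the deposited table holds a non-normalized bead intensity for each of 47319 probes on each array, on a linear scale, with no background subtraction visible in the values. The same deposited table gives a detection p-value per probe and array, set against the negative control beads. A further deposited table holds log2 values processed by the submitters. The submitters' processing notes name GenomeStudio, R 3.0.2 and lumi without stating the role of each. In that table the medians were 6.32 on every TC32 array and 6.31 on every SKNMC array, so the 2 lines appear to have been normalized separately. Each column matched its own array's log2 intensities best by Pearson correlation across probes (lowest 0.9969 with its own array, highest 0.9955 with another). Spearman correlation, taken only with the column's own array, was 0.9997 on each array. Fold changes in it were smaller than those from the re-normalized intensities, with slopes of 0.702 in TC32 and 0.685 in SKNMC over probes detected on every array at a p-value under 0.01. Its exact transformation is not given in the sources used here, and it served only as an alternative.

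The intensities were normalized with the neqc method of limma 3.58.1 in R 4.3.3. Background was estimated by normexp with the negative control signal inferred from the detection p-values, an offset of 16 was added, arrays were quantile-normalized and log2 was taken. Quantile normalization gives all arrays the same distribution, so a shift of most transcripts in one direction would not be seen. Probes detected (p-value under 0.05) on at least 3 of the 12 arrays were kept, which left 21753 probes. Of all probes, 30112 had a single gene symbol in the platform annotation, 8 had several and 17199 had none. Symbols were updated through the Entrez gene number for 30073 probes, with the table of the GRCh38.p14 assembly used for names only. The brightest detected probe, by its mean over all 12 arrays, stood for each gene, which gave 12171 genes. Of 3310 genes with several detected probes, 21 in TC32 and 14 in SKNMC had probes in opposite directions at an adjusted p under 0.05. No named gene was among them. There were 0 columns of sample values left unused, and 0 pairs of arrays held identical intensities. NR0B1 was on the list of genes to name and is not analysed here, because no probe carried its symbol in the annotation used. A further gene of that list, and the gene list and test tied to it, are not reported here.

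All 12 arrays entered one limma model with a mean for each of the 4 groups. The contrasts were NU7441 against vehicle in each line, the difference of these responses (TC32 minus SKNMC), and TC32 against SKNMC under vehicle. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 fold change of 1 or more, in the two-sided moderated test of limma. Errors on fold changes are standard errors (SE) from this model, in which each gene has a spread shared by all 4 groups. The groups differed in spread: 115 genes had an SD over 1 in SKNMC NU7441 and 0 in SKNMC vehicle. For such genes the SE and p-value can understate the spread in SKNMC and overstate that in TC32. A group in which a gene was detected on none of its arrays gives only a bound. The fold is then written as at least N-fold, the bright group's mean against the higher of the lowest detected signal and the gene's own signal on each dim array. The number of arrays limits the precision.

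Gene lists, 28 in all with 546 genes of which 451 were measured, were fixed before the data were examined, as were the groups, tests, thresholds and most alternative settings. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast, and again with the correlation estimated from the data. The EWS-FLI1 lists came from general knowledge of the fusion's targets. Genes to be named were set by a rule: per line the 10 largest rises and 10 largest falls among called genes that moved the same way in all 9 treated-by-vehicle array pairs, the 6 largest in each direction for the difference of responses, the 5 largest in each direction for the vehicle contrast, up to 4 members of each described list by absolute log2 fold change in that line, and a fixed set of genes that included PRKDC and the controls ACTB and GAPDH. Symbols that only number a locus or reading frame were skipped. A class of 212 non-polyadenylated RNA genes (ribosomal, small nuclear, small nucleolar, 7SK and Y RNAs) was defined from gene symbols after the data had been examined.

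The same functions were tested on simulated arrays of 12171 genes with the real gene-wise spread, on which 50 genes were changed in TC32 at each of 4 sizes. Of 50 genes changed by 0.5 on the log2 scale 0 were called, of 50 changed by 1 there were 21, of 50 changed by 1.5 there were 50 and of 50 changed by 2 there were 48. The 30 genes of the mitosis list were shifted by 0.5 in TC32 as well, and that list passed. Noise was drawn independently for each gene, so the list test was not tried under correlated genes. In the real data the correlation estimated for this list was 0.42. Normalization, the detection filter and the choice of probe were not simulated. Among the other 11941 genes, left unchanged, 4 were called. Alternatives covered the background correction, between-array normalization, detection filter, choice of probe, arrays in the fit, replicate number as a block, array weights, the variance prior, thresholds, gene list tests and each array left out in turn. Slide as a block could not be fitted, since slide was not given in the sources used here.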

Results

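Gene expression was measured in TC32 and SKNMC, established cell lines of Ewing sarcoma, a bone and soft tissue tumour driven by a fusion of EWSR1 with an ETS gene, most often FLI1. Cells received DMSO vehicle or 40 µM NU7441, an inhibitor of the DNA-dependent protein kinase encoded by PRKDC, for 48 h, with 3 arrays in each of the 4 groups. Between 17944 and 20148 probes were detected per array, and mean raw intensity ranged from 158 to 199. Across genes, arrays of one group correlated at 0.984 to 0.993 in TC32 vehicle, 0.966 to 0.989 in TC32 NU7441 and 0.993 to 0.994 in SKNMC vehicle. In SKNMC NU7441, replicates 2 and 3 correlated at 0.993 with each other and at 0.959 and 0.958 with replicate 1.

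The arrays of SKNMC NU7441 were not alike. CES1, a carboxylesterase, stood at log2 11.96 on replicate 1 and at 4.21 and 4.37 on replicates 2 and 3, against 11.32 ± 0.19 (SD, n = 3) in SKNMC vehicle. ITGB2, an integrin subunit, stood at 10.68 on replicate 1 and at 5.47 and 5.50 on the other two. The probe of 28S ribosomal RNA, RNA28SN5, went the other way, at 4.33 on replicate 1 and at 12.33 and 12.42 on replicates 2 and 3. In TC32 NU7441 it read 8.26, 9.33 and 12.69, and in vehicle 5.02 ± 0.14 (SD, n = 3) in TC32 and 4.37 ± 0.17 (SD, n = 3) in SKNMC. CES1 and ITGB2 were picked after their values were seen. Values in SKNMC are therefore given without replicates 2 and 3 where these 2 arrays decide them, from a fit that also leaves out TC32 NU7441 replicate 3, chosen after the data had been examined. In that fit the lone SKNMC NU7441 array is assumed to vary like the arrays of the other groups.

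**Figure D1:**
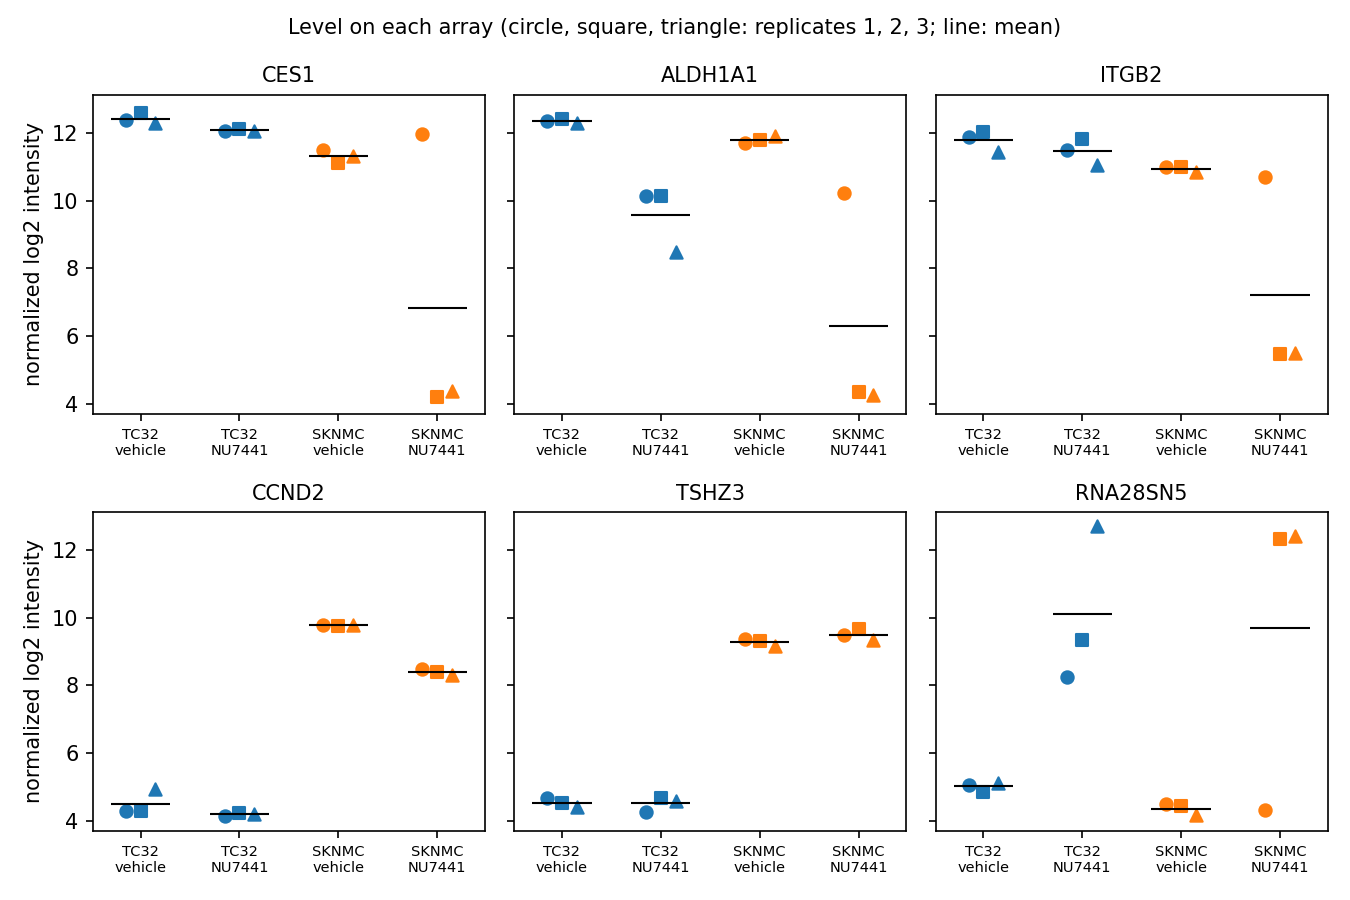
Normalized log2 intensity of 6 genes on each of the 12 arrays, with replicates 1, 2 and 3 as circle, square and triangle and group means as lines; the genes were chosen after their values were seen. CES1, ALDH1A1 and ITGB2 are low on SKNMC NU7441 replicates 2 and 3 (CES1 at 4.21 and 4.37), CCND2 and TSHZ3 separate the lines on all arrays, and RNA28SN5 is highest on TC32 NU7441 replicate 3 (12.69) and SKNMC NU7441 replicates 2 and 3.

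The first comparison asked how TC32 responded to NU7441. Cholesterol genes rose, with HMGCS1, an enzyme of the mevalonate pathway, up by a log2 fold change of 3.45 ± 0.13 (SE, n = 3 and 3) and INSIG1, a sterol sensor partner, up by 3.18 ± 0.20. Genes of amino acid stress fell, among them PCK2 at -3.61 ± 0.23, the mitochondrial phosphoenolpyruvate carboxykinase, and TRIB3, a pseudokinase induced by ATF4, at -3.59 ± 0.27. In all, 312 genes were higher and 476 lower with NU7441 of 12171 tested. The balance of directions rested on the quantile normalization: without between-array normalization 108 were higher and 1298 lower, and with median scaling 113 and 1193. PRKDC itself stood at -0.32 ± 0.14 and was not called (limma adjusted p = 0.116).

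Of the 10 named rises in TC32, 8 beyond HMGCS1 and INSIG1 were RNAs without a poly(A) tail. SNORD46 (4.10 ± 0.42), SNORA12 (3.82 ± 0.25) and SNORD13 (3.61 ± 0.23) are small nucleolar RNAs, and the U1 genes RNU1-3 (3.24), RNVU1-7 (3.21) and RNVU1-18 (3.19) share near-identical sequence, so their separate values are uncertain. SNORA79 was detected on no TC32 vehicle array and was at least 9.24-fold higher with NU7441. RNA28SN5 was at 5.08 ± 1.60 (adjusted p = 0.0314), a call that was lost on leaving out any TC32 vehicle array (5.13 or lower), NU7441 replicate 2 (5.46) or NU7441 replicate 3 (3.78). Its SD was 0.14 in TC32 vehicle, 2.31 in TC32 NU7441 and 4.64 in SKNMC NU7441. All of these enter the SE, so the spread in SKNMC bears on this call as well. Over the 212 non-polyadenylated RNA genes, 89 were called higher and 0 lower. The largest falls were DIRC3, a long non-coding RNA, at -4.44 ± 0.20 (detected on 1 of 3 NU7441 arrays), TNFSF13B, a B cell survival cytokine, at -3.74 ± 0.13, PCK2, TRIB3, the phosphodiesterase PDE7B at -3.48 (detected on 1 of 3 NU7441 arrays), the collagen COL3A1 at -3.43, the chemokine CXCL14 at -3.40, the G protein regulator RGS4 at -3.39 (detected on 2 of 3 NU7441 arrays), the Wnt antagonist DKK1 at -3.18 (detected on 1 of 3) and the protease PAPPA at -3.16.

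Of the 28 fixed gene lists, 7 passed camera in TC32. In the list of ATF4 and the integrated stress response, 23 of 28 measured genes fell and 0 rose, with a mean of -1.65 (adjusted p = 2.91e-22, and adjusted p = 0.0226 with an estimated correlation); after PCK2 and TRIB3 the largest were the hormone gene STC2 at -2.73 and the transcription factor ATF5 at -2.60. In cholesterol synthesis and uptake, 12 of 18 rose and 0 fell, with a mean of 1.56 (adjusted p = 1.45e-16, and adjusted p = 0.00043 with an estimated correlation), including DHCR7 at 2.54 and MSMO1 at 2.44, both sterol enzymes. In ER chaperones and the unfolded protein response, 3 of 17 fell (mean -0.48, adjusted p = 0.00221, and adjusted p = 0.0477 with an estimated correlation), namely XBP1, a transcription factor of that response, at -1.75, DNAJB9 at -1.08 and CRELD2 at -1.02, the last lost without TC32 vehicle replicate 2 (-0.92) or NU7441 replicate 1 (-0.87).

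In the mitosis list 23 of 30 genes fell and 0 rose in TC32 (mean -1.19, adjusted p = 2.15e-20), although the call was lost with the correlation estimated (adjusted p = 0.114). Its largest changes were CENPA, the centromeric histone, at -1.86 ± 0.20, the kinase AURKA at -1.63 ± 0.13, the kinetochore gene NDC80 at -1.61 and the topoisomerase TOP2A at -1.59. In lysosome and autophagy 4 of 22 rose (mean 0.40, adjusted p = 0.00221, and adjusted p = 0.114 with an estimated correlation), which were the sialidase NEU1 at 1.72, the autophagy receptor SQSTM1 at 1.57, the sterol carrier NPC2 at 1.51 and the kinase ULK1 at 1.18. In the heat shock list 2 of 14 rose (mean 0.38, adjusted p = 0.00963, and adjusted p = 0.137 with an estimated correlation; 0.0502 with the arrays of TC32 alone), HSPA1B at 2.00 and HSPA1A at 1.20, near-identical copies whose signals are uncertain; HSPA1A fell short of the fold minimum without TC32 vehicle replicate 3 (0.91) or NU7441 replicate 3 (0.9989). Without between-array normalization the median gene in TC32 shifted by -0.25, and the means of these 2 lists were -0.04 and -0.05, or 0.21 and 0.20 relative to that median. In fibroblast and mesenchymal markers 4 of 13 fell (mean -0.69, adjusted p = 0.007, and adjusted p = 0.114 with an estimated correlation; 0.0774 without between-array normalization and 0.0797 with median scaling), COL3A1, the smooth muscle actin ACTA2 at -1.53, the receptor PDGFRB at -1.33 (detected on 2 of 3 NU7441 arrays) and TAGLN at -1.03. ACTA2 lost its call without NU7441 replicate 3 (-1.33), and TAGLN without vehicle replicate 3 (-0.89) or NU7441 replicate 3 (-0.95). With fry, a planned test that passed more lists than camera did, the mitosis (adjusted p = 0.00012), lysosome (0.00036), heat shock (0.00068) and fibroblast (0.00022) lists kept their calls. Counts adjusted over the list alone were the same as over all genes for each of the 7 lists that passed camera in TC32.

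The second comparison put the same question to SKNMC. Stress genes fell here too, and cholesterol genes rose, by less than in TC32: PCK2 fell, at -3.75 ± 0.23 (SE, n = 3 and 3), as did TRIB3 at -3.72 ± 0.27, and HMGCS1 rose by 1.55 ± 0.13. In all, 419 genes were higher and 686 lower, and 260 and 888 without between-array normalization or 262 and 885 with median scaling. Without replicates 2 and 3 of SKNMC NU7441 these counts were 248 and 382, and without replicate 1 they were 635 and 907. PRKDC stood at -0.14 ± 0.14 (adjusted p = 0.493).

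Among the rises in SKNMC named by the rule on array pairs, the largest was COL7A1, an anchoring collagen, at 3.79 ± 0.31, followed by non-polyadenylated RNAs: RNU4-2 of the U4 small nuclear RNA at 3.75 (1.74 without replicates 2 and 3), RN7SK at 3.23 (1.53 without them), and the 5S ribosomal RNA RNA5S9 at 3.23 (1.06 without them, not called). RNA28SN5, with means of 4.37 in vehicle and 9.69 with NU7441, was not among them, since it read 4.33 on NU7441 replicate 1. The U1 genes RNVU1-7, RNVU1-18 and RNU1-3 stood at 2.77, 2.64 and 2.60, and at 1.40, 1.24 and 1.27 without replicates 2 and 3. Over the class, 50 of 212 genes were called higher and 0 lower. The histone gene H2BC5 rose by 2.84 ± 0.37 and HSPA1B by 2.66 ± 0.30. CXCL8, an inflammatory chemokine, was at 2.76 ± 0.96 (adjusted p = 0.0398) and lost its call on leaving out any SKNMC vehicle array (2.75 to 2.77) or replicate 2 (2.19) or 3 (2.05), and stood at 0.19 without both.

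Falls in SKNMC were led by ALDH1A1, a retinaldehyde dehydrogenase, at -5.51 ± 1.09 (detected on 1 of 3 NU7441 arrays), which was -1.57 without replicates 2 and 3. Its SD was 3.41 over the SKNMC NU7441 arrays and 0.10 in SKNMC vehicle. The SE, from a spread shared with the TC32 arrays, therefore understates the spread in SKNMC. MBD3L5 fell by 5.06 ± 0.50; it has near-identical paralogs, so its own share of the signal is uncertain. ACTA2 (-4.38 ± 0.42), the retinoid enzyme DHRS3 (-3.91) and the cell adhesion gene CEACAM6 (-3.86) were each detected on 1 of 3 NU7441 arrays. TXNIP, a thioredoxin-binding protein, was at -3.84 ± 0.32. TGFBI, an extracellular matrix protein, was at -4.15 ± 1.09 and -0.11 without replicates 2 and 3, and its call was lost on leaving out replicate 2 (-3.26) or 3 (-3.02) alone. The SKNMC NU7441 arrays read 10.89, 5.07 and 4.60 for TGFBI, so its SE has the same limit as that of ALDH1A1. The matrix-binding IGFBP5 was at -3.82 and at -0.95 without both, and CXCL14 was at -4.11 (detected on 1 of 3 NU7441 arrays) and -2.64 without both.

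In SKNMC 10 lists passed camera. In ATF4 and the integrated stress response 22 of 28 genes fell (mean -1.74, adjusted p = 7.94e-20, and adjusted p = 0.0265 with an estimated correlation), with STC2 at -3.60 and the serine enzyme PSAT1 at -2.41. In cholesterol synthesis and uptake 6 of 18 rose (mean 0.57, adjusted p = 0.000625, and adjusted p = 0.0265 with an estimated correlation), with LSS at 1.59, HSD17B7 at 1.34 and INSIG1 at 1.11. In fibroblast and mesenchymal markers 6 of 13 fell (mean -1.20, adjusted p = 1.51e-06, and adjusted p = 0.0265 with an estimated correlation), with the proteoglycans LUM at -2.17 (detected on 1 of 3 NU7441 arrays) and DCN at -1.69 beside ACTA2. The other 7 calls were lost with the correlation estimated. With fry, which passed more lists than camera did, all of them but that of DNA replication (adjusted p = 0.0543) were kept. The means without NU7441 replicate 1 were -0.78 for mitosis, -0.52 for DNA replication, -0.70 for EWS-FLI1-activated and -1.24 for EWS-FLI1-repressed genes. For lysosome, NF-kB and ER chaperones they were 0.30, 1.19 and -0.47. Each but that of lysosome was larger in size than with all arrays. In mitosis 6 of 30 fell (mean -0.66, adjusted p = 3.73e-07, and adjusted p = 0.309 with an estimated correlation), including HMMR at -1.49, CDC25C at -1.32, AURKA at -1.24 and AURKB at -1.20. Without replicates 2 and 3 the mean was -0.42, and CDC25C (-0.60) and AURKB (-0.57) were not called. In DNA replication and S phase 0 of 33 were called, with a mean of -0.35 (adjusted p = 0.00524, and adjusted p = 0.576 with an estimated correlation) that was -0.006 without replicates 2 and 3 (adjusted p = 0.927) and -0.24 without replicate 3 alone (adjusted p = 0.0576). Among EWS-FLI1-activated genes 8 of 30 fell (mean -0.57, adjusted p = 0.00104, and adjusted p = 0.158 with an estimated correlation), with UPP1 at -2.51, LIPI at -1.70 and GSTM4 at -1.62, each detected on 1 of 3 NU7441 arrays, and CAV1 at -1.68. Without replicates 2 and 3 the mean was -0.30, LIPI stood at -1.05, and CAV1 (-0.67) and GSTM4 (0.34) were not called. GSTM4 also lost its call on leaving out any SKNMC vehicle array (-1.65 to -1.58) or replicate 2 (-1.15) or 3 (-1.10). It kept its call without replicate 1 (-2.595). Among EWS-FLI1-repressed genes 7 of 18 fell and 1 rose (mean -0.97, adjusted p = 0.012, and adjusted p = 0.309 with an estimated correlation), or 8 and 1 adjusted over the list alone, so both EWS-FLI1 lists moved downward; without replicates 2 and 3 the mean was -0.44. CCN2 stood at -3.70 and, without replicates 2 and 3, at -1.17 and not called (adjusted p = 0.154), and IGFBP7, detected on 1 of 3 NU7441 arrays, at -2.15 and -0.87, not called. In lysosome and autophagy 5 of 22 rose and 1 fell (mean 0.37, adjusted p = 0.00295, and adjusted p = 0.158 with an estimated correlation), NEU1 at 1.93 and ULK1 at 1.32 (0.99 without replicates 2 and 3, not called) among the rises and the protease CTSL at -2.59 (-1.13 without replicates 2 and 3) the fall. In NF-kB and inflammatory genes 6 of 10 rose and 1 fell (mean 0.90, adjusted p = 0.0121, and adjusted p = 0.309 with an estimated correlation), with NFKBIA at 1.59, NFKB1 at 1.30 and RELB at 1.21, the last lost without replicate 2 (0.99) or 3 (0.94). Without both the mean was 0.32 (adjusted p = 0.221), and NFKB1 (0.49) and RELB (0.25) were not called. In ER chaperones 2 of 17 fell (mean -0.43, adjusted p = 0.0484, and adjusted p = 0.158 with an estimated correlation), XBP1 at -2.55 and PDIA6 at -1.09. The list's call was lost on leaving out any of 8 single arrays (means over all arrays left out in turn -0.47 to -0.39), with replicate number as a block (adjusted p = 0.0567), with the strict detection filter (0.0793), with the arrays of SKNMC alone (0.0732), without non-polyadenylated probes (0.0581) and without replicates 2 and 3 (0.062). PDIA6 stood at -0.04 without replicates 2 and 3, and its call was lost without vehicle replicate 1 (-1.12) or 2 (-0.996) or NU7441 replicate 2 (-0.82) or 3 (-0.84). Apart from the EWS-FLI1-repressed genes, counts adjusted over the list alone were the same as over all genes for these 10 lists.

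**Figure D2:**
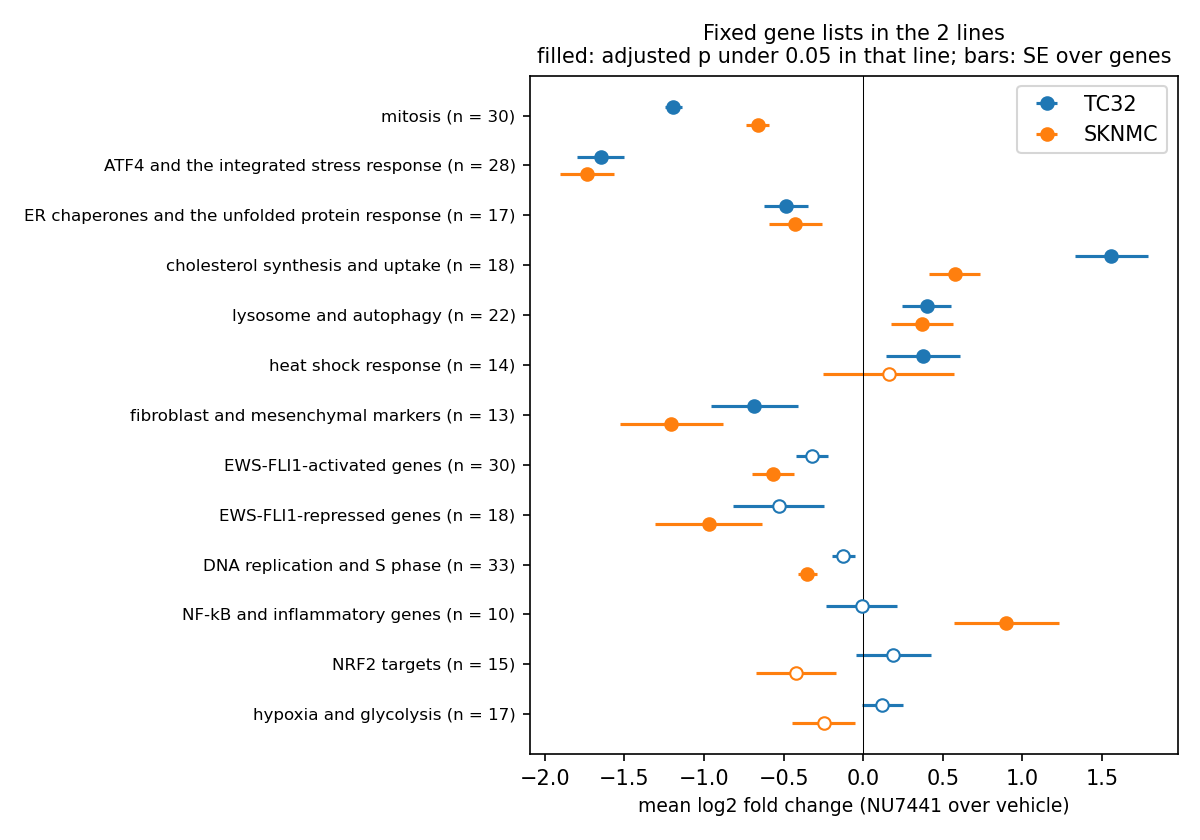
Mean log2 fold change (NU7441 over vehicle) of each fixed gene list that passed camera in at least 1 contrast, in TC32 and SKNMC; bars are the SE over the genes measured, n is their number, and filled points passed in that line. The ATF4 list lies at -1.65 and -1.74, the cholesterol list at 1.56 and 0.57 and the mitosis list at -1.19 and -0.66. Without between-array normalization the means of the lysosome and heat shock lists in TC32 turn to -0.04 and -0.05.

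Genes fixed in advance for their part in Ewing sarcoma or the cell cycle mostly did not pass. EWSR1 stood at 0.62 in TC32 (adjusted p = 0.0042, under the fold minimum) and 0.28 in SKNMC, FLI1 at 0.02 and 0.39, NKX2-2 at 0.72 and -0.11, CCND1 at -0.01 and -0.19, and MDM2 at -0.12 in TC32 (detected on 2 vehicle arrays and 1 NU7441 array), and none was called. CDKN1A, a cyclin-dependent kinase inhibitor, rose by 1.86 ± 0.22 in TC32 (adjusted p = 4.34e-05) and was at 0.61 ± 0.22 in SKNMC (adjusted p = 0.0434, under the fold minimum). The list of non-homologous end joining, the repair pathway of PRKDC, did not pass camera in either line. Its means were -0.05 (adjusted p = 0.589) in TC32 and 0.16 (median below 0, adjusted p = 0.586) in SKNMC. Of its 10 measured genes, 0 were called in TC32 and 1 rose in SKNMC. In TC32 the EWS-FLI1-activated genes had a mean of -0.32 (5 of 30 fell, adjusted p = 0.0882) and the EWS-FLI1-repressed genes -0.53 (2 of 18 rose and 3 fell, or 2 and 4 adjusted over the list alone, adjusted p = 0.287). In TC32 the stress-induced cytokine GDF15 fell, detected on no NU7441 array and at least 3.74-fold lower, and the stress gene SESN2 fell, at -1.08 (detected on 1 of 3 NU7441 arrays). SESN2 missed the fold minimum without vehicle replicate 3 (-0.9948) or NU7441 replicate 2 (-0.96). The controls ACTB (0.62 and -0.11) and GAPDH (-0.28 and -0.12) were not called.

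The responses of the 2 lines were then set side by side. Across the 12171 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.686, and at 0.763 over the 1495 genes called in either line. Of the genes called higher, 148 were shared, where independent lists would share 10.7, and of those called lower 248 were shared, where 26.8 would be. The 2 genes called higher in TC32 and lower in SKNMC were HSPA12A (1.28 and -1.001) and THEM6 (1.003 and -1.20), named after their values were seen, and 0 genes did the reverse. The lines have no arrays in common. The mark (2) on the vehicle titles is common to both, so their agreement cannot tell NU7441 apart from a possible separate run.

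**Figure D3:**
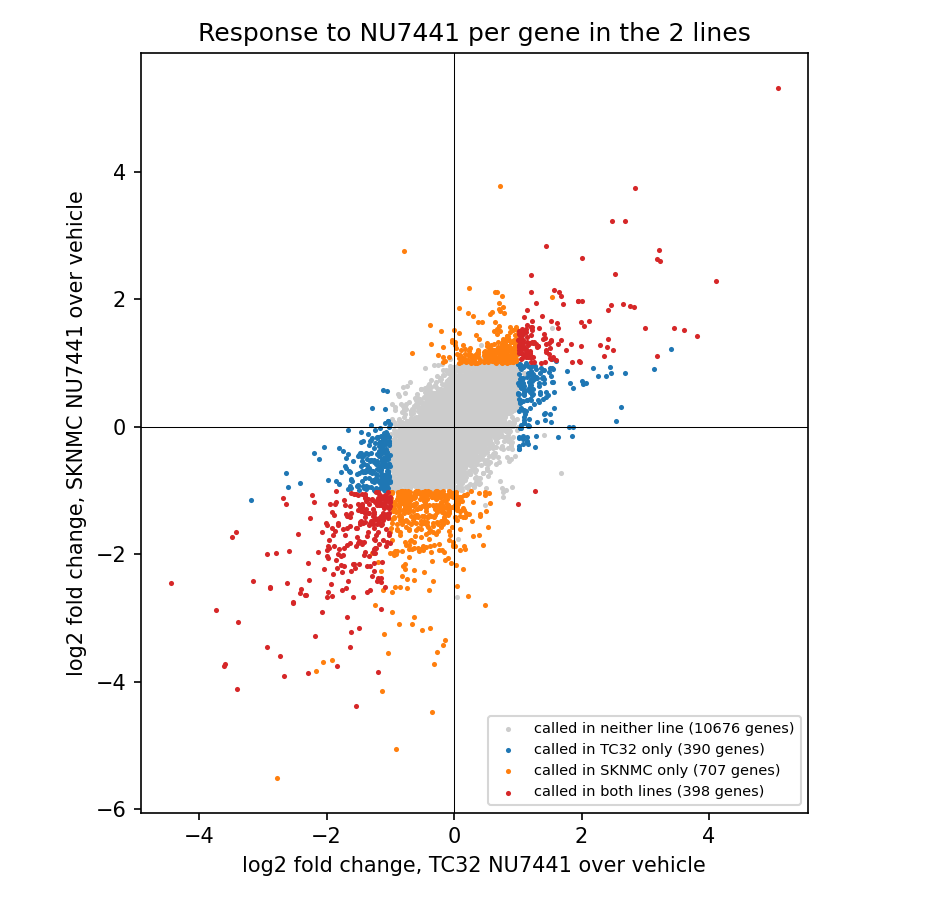
Log2 fold change of each of 12171 genes with NU7441 in TC32 (x axis) and SKNMC (y axis), one point per gene, coloured by the line or lines in which it was called. Most called genes lie in the lower left and upper right quadrants, with r = 0.686 across all genes.

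The difference of responses was called for 225 genes, 161 with a larger value in TC32 and 64 with a larger value in SKNMC. This count rested on single arrays: it was 778 without SKNMC NU7441 replicate 1 and 98 without SKNMC vehicle replicate 2, and 384 without the 3 arrays of highest 28S signal. Cholesterol genes rose more in TC32, with a mean difference of 0.99 (adjusted p = 1.25e-12, and adjusted p = 0.00105 with an estimated correlation) and 8 of 18 genes called, also when adjusted over the list alone, led by DHCR7 at 2.45, INSIG1 at 2.06 and HMGCS1 at 1.90. Named for a larger value in TC32 was ACTA2 (2.85, and 1.61 without the 3 arrays), which fell further in SKNMC. The call of ACTA2 was lost on leaving out any of 9 single arrays, with values of 2.44 without SKNMC NU7441 replicate 3 to 2.88 without SKNMC vehicle replicate 2. Named for a larger value in SKNMC were COL7A1 (-3.06), DIRC3 (-1.98), H2BC21 (-1.95, and -1.28 without the 3 arrays) and SELENOP (-1.82, and -1.01 without them). H2BC21 lost its call on leaving out any of 9 arrays (-2.02 to -1.65), and SELENOP without TC32 vehicle replicate 2 (-1.70) or SKNMC vehicle replicate 2 (-1.80). For 7 further genes named by the rule a group lay at background, so the size of the difference is not determined. MBD3L5, MBD3L3, MBD3L4 and MBD3L2, near-identical paralogs of uncertain share, fell in SKNMC and were detected on no TC32 NU7441 array. BTBD17 fell in SKNMC and was detected on no TC32 vehicle array, and CXCL10 rose in SKNMC and was detected on no TC32 array. ABCA1 was detected on no NU7441 array of either line, being at least 5.46-fold lower than vehicle in TC32 and at least 1.33-fold lower in SKNMC.

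Under vehicle, 518 genes differed between the lines, 167 higher in TC32 and 351 lower. Higher in TC32 were the receptor kinase MERTK by 2.88 ± 0.20, SEMA3A by 2.65, CEACAM6 by 2.64, NCAM1 by 2.32 and SCG2 by 2.21. Lower were the cyclin CCND2 at -5.27 ± 0.16 (detected on 1 of 3 TC32 vehicle arrays), MBD3L5 at -5.20 (detected on 2 of 3), TSHZ3 at -4.76 (detected on 2 of 3) and BHLHE22 at -4.40. NCKAP1L, a regulator of the actin cytoskeleton in blood cells, was detected on no TC32 array and was at least 18.7-fold higher in SKNMC vehicle. Of 1234 genes at log2 9 or more in TC32 vehicle, 0 were undetected on all SKNMC vehicle arrays, while 12 were detected on neither replicate 2 nor 3 of SKNMC NU7441. In the reverse direction, 0 genes at log2 9 or more in SKNMC vehicle were undetected on all TC32 vehicle arrays.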

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

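The tests of the transcripts missing from SKNMC NU7441 replicates 2 and 3 and of the non-polyadenylated RNAs were chosen only after the results were seen, and the counts of other splits of the arrays before.

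The response to NU7441 differed between the lines for 225 genes by the test of the difference itself. Of 100 splits of the arrays, drawn from 200 possible and the real one included, 9 gave as many genes. Labels were reassigned within each line independently, so some splits leave 1 line separated by treatment and mix the other. Such splits carry the response of that line, so their share cannot decide on chance, which is not excluded for this count. The highest other split called 3079 genes; it exchanged vehicle and NU7441 in a single line, which turns a response shared by the lines into a difference between them, and the highest without it called 1041. For gene lists, 7 passed for the difference, 31 of the 100 splits gave as many and the highest other gave 15. The same limit holds there, and chance is not excluded either. For the other comparisons 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real counts were 788 genes in TC32, 1105 in SKNMC and 518 between vehicle-treated lines, with the real split, 1 of 10, the only one as large each time and 0 genes in the highest other. For lists the real counts were 7 in TC32 and 10 in SKNMC, the highest others 8 and 10, and 4 of 10 splits were as large in each. The list counts therefore did not set the real split apart. Mixed splits hold unequal numbers of treated arrays on their sides and so keep part of the response.

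Beside cholesterol synthesis (mean difference, TC32 minus SKNMC, 0.99), the lists whose response differed were mitosis at -0.53 (adjusted p = 2.86e-08, and adjusted p = 0.564 with an estimated correlation), NF-kB and inflammatory genes at -0.91 (0.00891 and 0.564), fibroblast and mesenchymal markers at 0.52 (0.021 and 0.451), DNA replication at 0.22 (0.0276 and 0.742), NRF2 targets at 0.61 (0.0324 and 0.661) and hypoxia and glycolysis at 0.37 (0.0463 and 0.661). Without the 3 arrays of highest 28S signal, DNA replication turned to -0.25 with a call in the other direction (adjusted p = 0.028) and NRF2 targets to -0.25 (0.248), while NF-kB at -0.38 (0.199) and fibroblast markers at 0.34 (0.11) were no longer past the threshold. Hypoxia was lost without between-array normalization (0.09, adjusted p = 0.123), with median scaling (0.12, 0.139), with 6 other choices of processing, among them the submitters' values (0.0595), and without any of 7 single arrays (highest adjusted p = 0.175). NRF2 targets were lost with those values (0.36, 0.0812), no background correction (0.0886), normexp (0.0646) and the strict filter (0.0562), and without any of 5 single arrays (highest 0.295). NF-kB was lost without between-array normalization (0.051), and fibroblast markers with the strict filter (0.0562) or without TC32 NU7441 replicate 1 (0.47, 0.0619). DNA replication was lost without any of 4 single arrays (highest 0.456). With fry, mitosis (0.136), NF-kB (0.136), hypoxia (0.313), NRF2 targets (0.348) and DNA replication (0.45) were lost. Adjusted over the list alone, 2 genes of mitosis, 4 of NF-kB and 2 of NRF2 targets differed. Of 13 fibroblast genes, ACTA2 (2.85), LUM (2.20) and DCN (1.63) were called for a larger value in TC32 and COL3A1 (-1.78) in SKNMC. LUM and DCN were each undetected throughout a group, so part of this list's mean depends on the background. The median of the list was 0.39. Among named genes, larger values in TC32 were found for SNORA12 (2.39), SNORD13 (2.09), HMGCS1 (1.90), INSIG1 (2.06), DHCR7 (2.45), MSMO1 (1.51), SQSTM1 (1.03) and CDKN1A (1.25), which rose in TC32. They were also found for ACTA2 (2.85, and 1.61 without those 3 arrays), TXNIP (2.64), UPP1 (1.66) and BHLHE22 (1.40), which fell further in SKNMC. Larger values in SKNMC were found for DIRC3 (-1.98), COL3A1 (-1.78), SEMA3A (-1.16) and DNAJB9 (-1.36), lower with NU7441 in TC32, and for COL7A1 (-3.06), H2BC21 (-1.95), SELENOP (-1.82), NFKB1 (-1.66) and TP53INP1 (-1.10), which rose in SKNMC. For 12 more genes a group was detected on none of its arrays, so the fitted difference depends on the background and does not show by how much, or whether, the responses differ: MBD3L5 (4.15), MBD3L3 (3.25), MBD3L4 (3.24), MBD3L2 (3.21), BTBD17 (2.88), LUM (2.20), DCN (1.63), CCND2 (1.08), PDE7B (-1.75), ABCA1 (-1.91), CXCL10 (-1.79) and GDF15 (-1.78). Probes without a single gene symbol, 5313 of them detected, were outside the gene tests; 192 passed in TC32, 116 of them higher with NU7441, and 310 in SKNMC, 195 of them higher.

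In SKNMC NU7441, 53 genes were lower by 2 or more on the log2 scale on replicates 2 and 3 than on replicate 1, and 18 were higher. TC32 RNA in place of SKNMC RNA on replicates 2 and 3 is argued against, since at least 61.7% of 303 genes detected in SKNMC vehicle and not in TC32 vehicle were detected there, against at most 20.1% on a TC32 NU7441 array. An even dilution by ribosomal RNA as the whole cause is argued against as well, since without between-array normalization the 612 genes at log2 10 or more on replicate 1 had a median difference of -0.24 (SD 0.67). A loss of these transcripts in 2 of 3 treated samples, which was not tested, stays open, and so does TC32 RNA on replicate 1, or on it and the SKNMC vehicle arrays. TC32-specific genes were detected on replicate 1 at 29.6%, on replicates 2 and 3 at 14.8% and 18.5%, and on the TC32 NU7441 arrays at only 42.6% to 51.9%. Of the 53 genes, 3.77% lay by over 1 above the highest TC32 array on replicate 1, and 3.77% above the highest TC32 vehicle array in SKNMC vehicle, where 1.63% and 2.65% of other genes did, too few for either test to decide. Of the 53, only 4 on replicate 1 and 8 in SKNMC vehicle exceeded TC32 at all (23.5% and 35.8% of other genes), as such RNA would give. The 2 genes by over 1 above TC32 in SKNMC vehicle are not what a single share of it would give. They were TGFBI (10.96 or more, at most 9.98 in TC32 vehicle) and PVT1 (mean 9.27, at most 5.91). On replicate 1 PVT1 stood at 8.85, against at most 6.36 on a TC32 array. Nor would a single share give the levels of 12 genes abundant in TC32 vehicle and undetected on replicates 2 and 3 (-2.64 to -0.56 in SKNMC vehicle relative to TC32 vehicle, -2.99 to 0.65 on replicate 1 relative to TC32 NU7441).

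Of the 212 non-polyadenylated RNA genes, a class set after the data were seen and given no test as a set, 89 were called higher with NU7441 in TC32 and 50 in SKNMC, and 0 lower. Between-array normalization as the whole cause is argued against, since the lowest class mean over both lines and both other scalings was 0.62. So is TC32 NU7441 replicate 3 alone, since the mean without it was 0.94. In SKNMC the class mean was 0.34 on replicate 1 and 0.89 on replicates 2 and 3, so the part of the rise that rests on those 2 arrays cannot be told apart from an effect of NU7441. An effect on these RNAs in the cells and a difference in the RNA or its labelling both stay open, as neither was tested.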

How the results depend on the processing

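Leaving out the 3 arrays of highest 28S signal together was chosen after the data had been examined, as was removing non-polyadenylated probes before normalization; the other alternatives were planned. Of 288 list means with each array left out in turn, 262 kept their direction and side of the threshold and 26 were no longer past it; of 449 under other settings 392 kept both, 49 were no longer past it and 8 reversed. Of 2148 single-gene values with an array left out 2059 kept both, 64 were no longer past the threshold and 25 newly past it; of 2816 under other settings the numbers were 2547, 189 and 79, and 1 reversed. Genes higher and lower in TC32, higher and lower in SKNMC, differing in response and differing under vehicle numbered 93, 158, 132, 217, 58 and 160 with the submitters' values, 89, 156, 139, 221, 57 and 160 without background correction, and 122, 198, 179, 301, 78 and 213 with normexp. With the submitters' values fold changes were smaller (slopes 0.702 in TC32 and 0.685 in SKNMC) under the same fold minimum. The cause of the lower counts was not tested. Median scaling gave 113 higher and 1193 lower in TC32 and 262 higher in SKNMC, and no between-array normalization 108, 1298 and 260. The median gene then shifted by -0.22 and -0.25 in TC32, and the means of the lysosome list (-0.015 and -0.045) and heat shock list (-0.022 and -0.052) in TC32 and of DNA replication for the difference of responses (-0.047 and -0.076) reversed, although each stayed above 0 relative to the median gene (0.21, 0.20 and 0.08). No detection filter gave 144 genes differing in response, the strict filter 4 lists for that difference, and all probes 473 higher in TC32 and 669 in SKNMC, since more items were tested. Array weights gave 945 genes differing in response and r = 0.582; the cause was not tested. No fold minimum gave 1446, 1636, 1826 and 2059 genes and 1767 under vehicle, and treat 146 and 310 in TC32, 205 higher in SKNMC and 36 differing in response, as these change the threshold itself. Lists past the threshold in TC32, SKNMC and the difference numbered 3, 3 and 1 with an estimated correlation and 15, 17 and 2 with fry. Without the 3 arrays SKNMC had 248 higher and 382 lower and 384 genes differed in response, while DNA replication (-0.251) and NRF2 targets (-0.251) for the difference and GSTM4 in SKNMC (0.339) reversed; the cause was not tested. With each array left out, the ranges were 239 to 387 and 445 to 505 in TC32, 337 to 635 and 572 to 907 in SKNMC, 98 to 778 for differing response, 481 to 606 under vehicle, 0.612 to 0.705 for r, and 7 to 8, 8 to 11 and 4 to 10 for lists. For list means that lost a call, the ranges were -0.522 to -0.244 (DNA replication, SKNMC), -0.468 to -0.393 (ER chaperones, SKNMC), 0.093 to 0.397 (DNA replication, difference), 0.434 to 0.972 (NRF2 targets, difference), 0.280 to 0.516 (hypoxia, difference) and 0.459 to 0.632 (fibroblast, difference). Slide as a block was not run, as slide is unknown, and the all-probes setting gives no gene or list values. Fold changes of genes near background are limited by signal over background.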

Other observations

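All lists and tests below were chosen before the results were seen. The lists of the translation and energy machinery did not pass camera in either line, although 1 of 24 cytosolic ribosomal protein genes rose in SKNMC. With fry, oxidative phosphorylation (adjusted p = 0.0276 in TC32 and 0.0138 in SKNMC), interferon-stimulated genes (0.0219 and 0.00257) and FOXO targets (0.0278 and 0.0176) passed in both lines. Cytosolic ribosomal proteins passed fry in TC32 (0.0393) and the aryl hydrocarbon receptor list in SKNMC (0.00394). Values below are from camera. Cytosolic ribosomal proteins had means of 0.09 in TC32 (adjusted p = 0.530) and 0.08 in SKNMC (adjusted p = 0.545), ribosome biogenesis -0.03 (0.773) and -0.16 (0.225), and oxidative phosphorylation -0.18 (0.115) and -0.20 (0.117). Homologous recombination and Fanconi anaemia genes stood at -0.10 (0.698) and -0.20 (0.303), with 1 of 17 called higher and 1 lower in each line, also when adjusted over the list alone. Interferon-stimulated genes stood at -0.23 (0.358) and -0.33 (0.0912), FOXO targets at -0.20 (0.530) and -0.29 (0.522), and each of these lists had 2 of 16 genes lower in each line. The aryl hydrocarbon receptor list, with 3 genes measured, had means of 0.21 (0.589) and -0.80 (0.0572).

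Pro-death BCL2 family genes stood at 0.05 (camera adjusted p = 0.589) in TC32 and 0.01 (0.586) in SKNMC, and pro-survival members at -0.26 (0.558) and -0.15 (0.586). Measured were 9 pro-death genes, of which 1 fell in SKNMC, and only 4 pro-survival genes. MAPK feedback genes stood at 0.03 (0.773) and -0.31 (0.434), neuronal markers at -0.11 (0.735) and -0.39 (0.155), epithelial markers at -0.19 (0.589) and -0.47 (0.0897), and haematopoietic markers at 0.42 (0.530) and 0.60 (0.211). Of these, 13 MAPK feedback, 10 neuronal, 6 epithelial and 3 haematopoietic genes were measured. In SKNMC 2 MAPK feedback, 1 neuronal and 1 epithelial gene fell and 1 haematopoietic gene rose. In TC32 1 neuronal and 1 haematopoietic gene rose and 2 neuronal genes fell. With fry, neuronal (adjusted p = 0.00272) and epithelial markers (0.00192) passed in SKNMC. Haematopoietic markers passed fry in both lines (0.0254 in TC32 and 0.00192 in SKNMC). Under vehicle, 4 genes were detected on no TC32 vehicle array and on all SKNMC vehicle arrays among those named for other reasons: BTBD17 was at least 9.60-fold higher in SKNMC, the proteoglycan DCN at least 7.31-fold, LUM at least 4.74-fold and the chemokine CXCL10 at least 1.84-fold.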
